A study of Mus musculus with 2 samples.

How the data were processed

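Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out with an antibody to H3K27me3, the repressive histone mark laid down by Polycomb repressive complex 2, on mouse embryonic neural tube at day 11.5. Per the labels, the tissue came from mixed male and female embryos of the B6NCrl strain, 109 embryos for replicate 1 and 88 for replicate 2, and 2 technical replicates were merged in each biological replicate. Both samples belong to 1 group, so no comparison between groups was possible and the replicates give the only measure of spread.

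The authors deposited 4 peak lists in narrowPeak format on the mouse build mm10, 1 called on each replicate, 1 on the pooled replicates and 1 of replicated peaks. Per the file headers and the text deposited with each sample, the replicated list was derived from the other 3, and the peak lists of the replicates and of the pool share 2 further input files, which the text does not describe. The labels name the same control experiment for both samples, so part of the agreement between replicates could come from shared input files. The deposited fold per peak is a linear ratio of ChIP over control, and the deposited significance values are −log10 of a p-value and −log10 of a q-value for each peak. These are the authors' own values for each peak and were used to describe, rank or filter peaks. Between lists, they were compared as folds of overlapping peaks, as p-values at equal fold and as peak numbers by q. The aligner, the peak caller, their versions and the overlap that made a peak replicated are not given in the sources used here. Read depth is unknown from peak lists, so no interval that needs it is given. The deposited lists are not filtered on q: 17.3% of replicated peaks had a q-value above 0.05, and the lowest −log10 p in that list was 2.05.

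The overlap rule was examined on the lists themselves. All 18681 replicated peaks had the coordinates of a pooled peak. Of these, 14517 (77.7%) overlapped a peak of each replicate by 50% of either peak, against 0 of the 5120 pooled peaks that were left out. The other replicated peaks met a criterion that the sources used here do not state. A total of 1407 replicated peaks had no base in a peak of replicate 1 and 2431 had none in a peak of replicate 2, so that 14903 (79.8%) overlapped both deposited replicate lists.

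Coordinates were set against the GRCm38 patch 6 sequence, which has the chromosomes of mm10, and the GENCODE M21 annotation, with the 21938 protein-coding genes on chromosomes 1 to 19, X and Y. Replicate 1 had 2 peaks on unplaced scaffolds, which were left out. A transcription start site (TSS) was the 5' end of the gene. Other start sites of a gene were not examined, except that coding starts were also tried for Hox genes. A promoter was marked when at least 1 bp of a replicated peak lay within 2 kb of the TSS, a window of 4001 bp. CpG-rich segments were computed from the sequence as stretches of at least 500 bp with at least 55% GC and an observed over expected CpG ratio of at least 0.65. A promoter was CpG-rich when such a segment lay within 1 kb of its TSS. Peaks closer than 3 kb were joined into domains.

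Replicate peaks counted as shared when at least 50% of their length lay inside peaks of the other replicate. Each share of peaks was set beside 100 random placements of the same peak widths on the same chromosomes outside assembly gaps. A set of 18 gene lists was fixed by name before the data were examined, 17 of them with 382 gene symbols, of which 380 were in the annotation, and the olfactory receptors by their symbol stem, with 1135 genes. The symbols not found were second names of genes already listed. Each list was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 18 lists. Neighbouring genes share domains and genes are not independent replicates, so these p-values describe a list against other genes in these libraries. The Hox relation was Spearman's rho between covered promoter bases and paralog number over 39 genes, with paralog numbers permuted within each cluster 100000 times, two-sided. Intervals on shares are exact binomial at 95% and cover counting error only.

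Genes named in the text were members of the fixed lists, the 20 genes with the most replicated peak bases within 5 kb of the TSS, the genes inside the 10 longest domains and the genes nearest to the 10 peaks of highest fold. Genes outside these were chosen after their values were seen and are named as such. The alternatives were the pooled list, each replicate's own list, peaks with −log10 q of at least 5, promoter windows of 1 kb and 5 kb, at least 500 bp of covered promoter, CpG-rich promoters only, joining distances of 1 kb and 10 kb, and other rules for shared peaks. All choices except those named in the closing section as added were made before the data were examined.

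The list test was tested on simulated data over the 21938 genes. With 60% of the members marked, 94.5% of simulated lists of 12 genes and 100% of lists of 25 and of 40 genes had a p under 0.05, against 2.5%, 7.5% and 4.5% of random lists. The interval arithmetic was checked against a base-by-base count over 500 intervals. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.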

Results

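H3K27me3 was profiled by ChIP-seq in mouse neural tube at embryonic day 11.5, when the spinal cord and hindbrain hold patterned progenitors and early neurons. The series has 1 group with 2 biological replicates, each a pool of embryos. Replicate 1 gave 41355 peaks over 21.2 Mb and replicate 2 gave 29642 peaks over 16.3 Mb, a mean of 18.8 ± 3.497 Mb (SD, n = 2). The pooled list had 23801 peaks over 17.3 Mb. The replicated list, used below unless another is named, had 18681 peaks over 16.0 Mb, 0.606% of the assembled sequence, with a median width of 427 bp and a median fold over control of 3.52. The number of reads behind these lists is unknown, and the lists do not show which cells of the tissue carried the mark.

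The question set to the gene lists was which classes of genes carry the mark in this tissue. In the lists of patterning factors and signals other than Hox genes, 75% to 96.2% of promoters were marked, for factors of the neural tube and of other tissues, and 61.5% of Hox promoters were. Housekeeping and olfactory receptor promoters were almost free of the mark. Among all protein-coding genes, 3346 of 21938 (15.3%) had a marked promoter. Of the transcription factors that define progenitor domains of the neural tube, 25 of 26 were marked (96.2%, 95% interval 80.4 to 99.9%, adjusted p = 4.73e-19, Fisher's exact test). The exception, Gli3, a mediator of hedgehog signalling, had 0 bp covered in replicate 1 and 190 bp in replicate 2. Olig2, the factor of motor neuron progenitors, was covered over its whole 4001 bp window in both replicates with a fold of 13.4. Foxa2, a floor plate factor, was also wholly covered in both, with a fold of 12.7. Pax6 was covered over 3659 ± 245 bp (SD, n = 2) and Nkx2-2 over 3534.5 ± 17.7 bp (SD, n = 2). The weakest marked member, Irx5, had 528.5 ± 145 bp (SD, n = 2) and a fold of 3.46. Marked shares in the replicates' own lists were 96.2% and 100%.

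Factors of postmitotic spinal neurons were marked in 26 of 28 cases (92.9%, adjusted p = 6.67e-19, Fisher's exact test), at a median fold of 8.11. Isl1 and Mnx1, factors of motor neurons, had folds of 8.95 and 8.33, and Tal1, a factor of ventral interneurons, had 10.3. The unmarked members were Foxp1 and Foxp2, with 0 bp in either replicate. Factors of forebrain and midbrain, regions rostral to the spinal cord, were marked in 23 of 24 cases (95.8%, exact adjusted p = 1.14e-17), with Hesx1 the exception. Otx2 had a fold of 10.7 and Foxg1 of 8.57, and Six3 was wholly covered in both replicates. Both shares were the same in each replicate's own list.

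Factors of other germ layers were also marked more often than the remaining genes. Mesoderm, heart and muscle factors were marked in 24 of 28 cases (85.7%, adjusted p = 7.67e-16, Fisher's exact test), among them Tbx1 at a fold of 11.6, Nkx2-5 at 10.7 and Myod1 at 9.77. The unmarked members were Meox1 and the muscle regulators Myf5, Myf6 and Myog. Endoderm factors were marked in 17 of 20 cases (85.0%, exact adjusted p = 2.33e-11), with Cdx2, an intestinal factor, at a fold of 10.1 and Neurog3, a factor of pancreatic endocrine cells, at 12.8. Hnf1a, Hnf4a and Isx were not marked. Neural crest and peripheral neuron factors were marked in 9 of 12 cases (75%, exact adjusted p = 1.25e-05), including Foxd3, Phox2b and Sox10. Snai2, Runx3 and Sox9 were unmarked. Secreted patterning signals and their antagonists were marked in 31 of 34 cases (91.2%, exact adjusted p = 1.43e-21). Shh, the floor plate signal, had a fold of 10.8, and Wnt1, expressed along the dorsal midline, had 10.8. Wnt8b, Fgf10 and Fgf20 carried no replicated peak.

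Genes general to neural progenitors or to neurons were marked more often than the remaining genes, at a low median fold. Of 24 pan-neural progenitor and neuron genes, 12 were marked (50%, 95% interval 29.1 to 70.9%, adjusted p = 1.25e-04, Fisher's exact test), at a median fold of 3.46. Ina, a neurofilament component, had the highest fold of the list, 7.75, and the progenitor factor Sox1 had 5.96. Sox2 had a fold of 3.85 and Tubb3, the neuronal tubulin, 3.27, and Nes, Vim, Sox11 and Gap43 had no covered base in either replicate. With only peaks of −log10 q of at least 5, the share was 16.7% (adjusted p = 0.142, Fisher's exact test).

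No housekeeping gene of 26 carried a replicated peak (95% interval 0 to 13.2%, adjusted p = 0.0349, Fisher's exact test), and 1 of them, Reep5, had a peak in replicate 1. This call was lost with peaks of −log10 q of at least 5, a 1 kb window, 500 bp of coverage, and peaks found in both replicates' lists (adjusted p = 0.31, 0.0613, 0.0847 and 0.0581, Fisher's exact test). Olfactory receptor genes were marked in 1 of 1135 cases (0.0881%, exact adjusted p = 8.06e-81), and in replicate 1's own list 2 were marked (0.176%). Only 1 of the 1135 has a CpG-rich promoter, so that the call was lost among CpG-rich promoters (adjusted p = 1, Fisher's exact test). Imprinted genes, expressed from 1 parental allele, were marked in 10 of 26 cases (38.5%, exact adjusted p = 0.00556), among them Slc22a3 at a fold of 12.5, Kcnq1 at 8.73 and Igf2 at 6.55. Peg3, Snrpn, Mest and Igf2r were not. Cyclin-dependent kinase inhibitors were marked in 4 of 6 cases (66.7%, adjusted p = 0.00938, Fisher's exact test): Cdkn2a, with 3915 ± 63.6 bp (SD, n = 2) and a fold of 10.99, Cdkn2b at 12.1, and Cdkn2c and Cdkn1a with 650 and 126 bp. Among CpG-rich promoters the adjusted p was 0.0714 for imprinted genes and 0.112 for these inhibitors, and 0.24 for the inhibitors with a 1 kb window (Fisher's exact test).

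The other 5 lists did not pass the threshold against the remaining genes. Marked shares were 1 of 14 glial differentiation genes (Mbp), 3 of 20 genes of blood, vessels and connective tissue (Kdr, Klf1 and Col1a1) and 1 of 15 germline genes (Prdm14), with adjusted p = 0.758, 1 and 0.758 by Fisher's exact test. The glial share was 28.6% in replicate 1's own list and 14.3% in that of replicate 2, and the germline share 13.3% and 6.67%, none past the threshold (adjusted p = 0.573, 1, 0.783 and 0.555, Fisher's exact test). Pluripotency genes were marked in 4 of 12 cases (33.3%, exact adjusted p = 0.123): Pou5f1, Klf4, Tdgf1 and Utf1. That list passed the threshold in replicate 1's own list (50%, adjusted p = 0.033) and with peaks of −log10 q of at least 5 (33.3%, adjusted p = 0.0146, Fisher's exact test). Polycomb genes were marked in 7 of 26 cases (26.9%, exact adjusted p = 0.123), among them Cbx4 at a fold of 10.1 and Cbx8 at 9.86, both of which encode chromodomain proteins. The catalytic subunits Ezh1 and Ezh2 and their partners Eed and Suz12 had no covered base in either replicate.

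**Figure D1:**
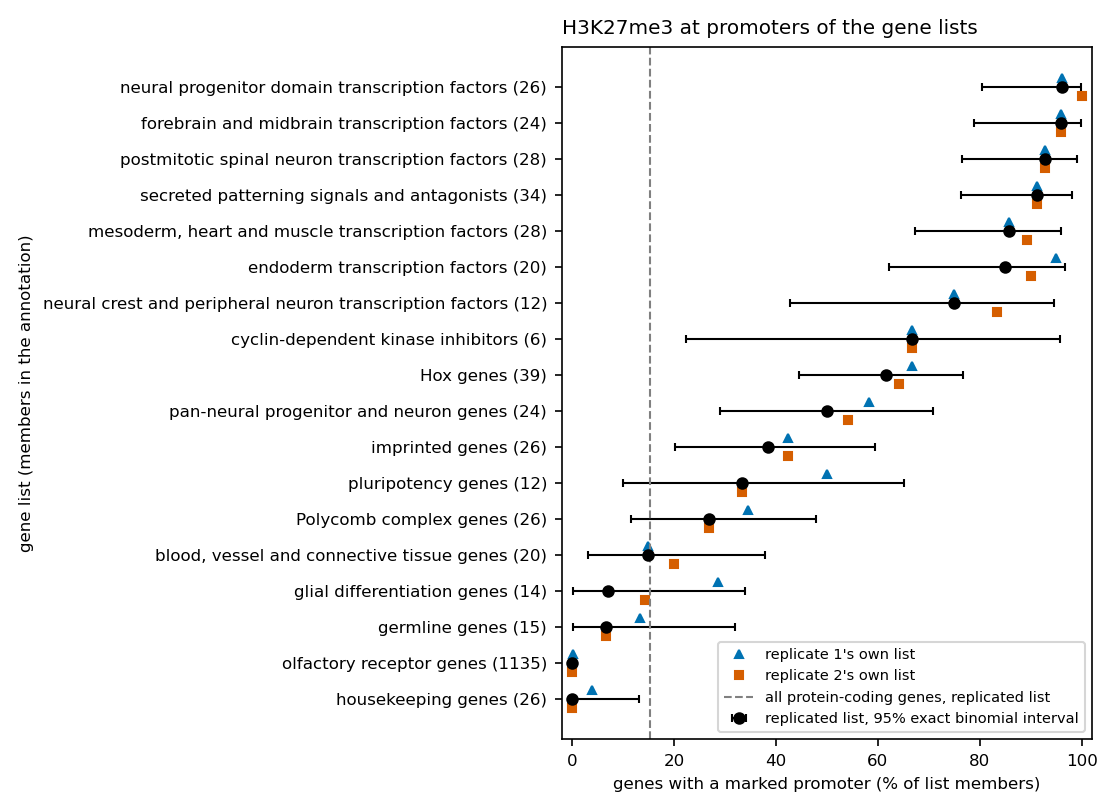
Share of each list's members with a marked promoter (x axis, percent) for the replicated list (black, 95% exact binomial interval) and each replicate's own list (triangles, squares), with the number of members in parentheses and the 15.3% of all protein-coding genes as a dashed line. The developmental factor and signal lists other than Hox genes (61.5%) lie between 75% and 96.2%, and housekeeping and olfactory receptor genes lie at 0 and 0.0881%.

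The 39 Hox genes set the axial identity of the neural tube, and low paralog numbers are expressed further rostrally. Genes of high paralog number were covered by the mark and genes of low number mostly were not. Of the genes of paralog groups 9 to 13, 15 of 16 were marked, with a mean over the genes of 3296 ± 219 bp of the 4001 bp window (SD of the replicates, n = 2). In groups 5 to 8, 6 of 11 were marked with 750.4 ± 230.3 bp, and in groups 1 to 4, 3 of 12 with 184 ± 60.8 bp (SD, n = 2). Covered length rose with paralog number (Spearman's rho = 0.798, Pearson's r = 0.816, permutation p = 1e-05, the smallest that 100000 draws can give). Genes of a cluster are neighbours that can share a domain and are not independent. The permutation does not allow for this, so its p describes these genes in these libraries only. As a list, Hox genes were marked in 24 of 39 cases (61.5%, adjusted p = 1.26e-10, Fisher's exact test).

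The clusters differed in the share of their gene span that was covered. That share also depends on which paralogs a cluster holds and how far apart they lie, so it does not measure how far the mark reached. On the map of the clusters, 53.0% of Hoxc (chromosome 15, 102921103 to 103036852) was covered, 35.1% of Hoxd (chromosome 2, 74668310 to 74765142), 26.8% of Hoxa (chromosome 6, 52155590 to 52260880) and 14.5% of Hoxb (chromosome 11, 96194316 to 96368256). In the replicates' own lists the means were 52.8 ± 5.61%, 34.3 ± 5.11%, 27.8 ± 4.49% and 15.2 ± 3.29% (SD, n = 2), and each cluster was lower in replicate 2. Within clusters, rho was 0.881 for Hoxc, 0.891 for Hoxd, 0.858 for Hoxa and 0.216 for Hoxb. In Hoxb, the promoter of Hoxb13 was wholly covered in both replicates, and Hoxb9 had 0 replicated bases but 787 and 207 bp in the replicates' own lists. Hoxb1 at the opposite end had 1066 replicated bp and fewer in each replicate's own list, fewest in replicate 2. Hoxc5 counted as covered over 3550 bp because its annotated 5' end lies 46639 bp from its coding start, where 0 bp were covered. Hoxc6 and Hoxa3 also had 0 bp at their coding starts, against 670 and 202 bp. Taking the coding start for all 39 genes gave rho = 0.811 (permutation p = 1e-05). Groups 5 to 8 then had 4 of 11 marked with 345.8 ± 98.0 bp, groups 1 to 4 had 2 of 12 with 165.3 ± 86.7 bp, and groups 9 to 13 had 15 of 16 with 3255 ± 346 bp (SD, n = 2).

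**Figure D2:**
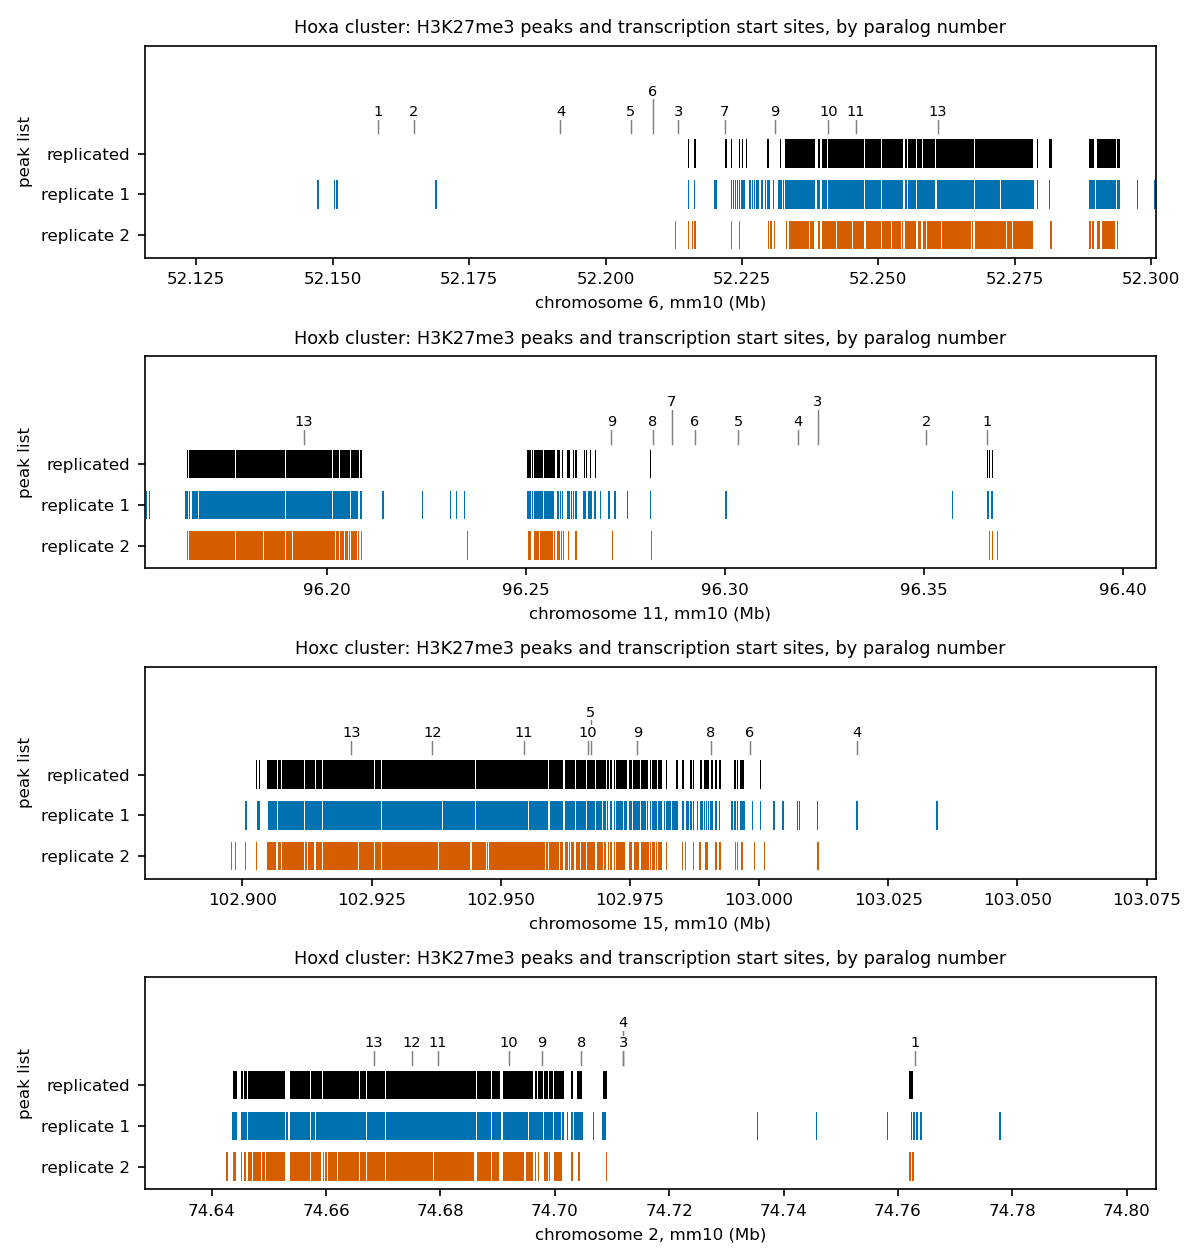
H3K27me3 peaks of the replicated list (black) and of each replicate (blue, orange) across the Hox clusters and 40 kb on either side, against mm10 position in Mb, with ticks for annotated transcription start sites and their paralog numbers. Peaks form nearly unbroken blocks over paralogs 10 to 13 of Hoxa, Hoxc and Hoxd, and 14.5% of Hoxb is covered.

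Joining peaks closer than 3 kb gave 6259 domains, of which 458 were at least 10 kb and 185 at least 20 kb long. The longest spanned 110 kb on chromosome 7 (49615129 to 49725419) and held the promoter of Dbx1, a factor of progenitors midway along the dorsoventral axis. Replicate peaks covered 74.5 ± 4.06% of the length of this domain (SD, n = 2). Next came 94.4 kb over Hoxc13 to Hoxc8, 89.1 kb over the start of Pax3 on chromosome 1 (78131251 to 78220333), 82.9 kb at Nfix on chromosome 8 (84732030 to 84814914) and 73.2 kb over Zic1 and Zic4 on chromosome 9 (91348894 to 91422061). The remaining domains among the 10 longest were 61.0 kb from Evx2 to Hoxd8, 59.6 kb at Dmbx1, 52.1 kb from Hoxa9 to Hoxa13, and 49.95 kb over Unc13a, Jak3, Insl3 and B3gnt3. A 52.3 kb domain on chromosome 4 (148854551 to 148906827) lay inside the gene Casz1 and held no 5' end of a protein-coding gene. The domain ranked first depended on the list and the joining: it lay at Hoxc (103.4 kb) without replicate 1, at Nfix (114.4 kb) without replicate 2, at Hoxc (94.4 kb) with peaks found in both replicates' lists, and at Dbx1 again in the pooled list. It was at Nfix with peaks of −log10 q of at least 5 (70.9 kb) or a distance of 1 kb (81.2 kb), and on chromosome 16 with 10 kb (222.6 kb). The number of domains also moved from 6259, to 10412 without replicate 1, 16998 without replicate 2 and 2335 with peaks of −log10 q of at least 5.

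Of the 20 genes with the most covered bases within 5 kb of the start site, 14 were members of the fixed lists. In 14 genes all 10001 bp were covered, among them Olig2, Onecut3, Hmx1, Skor2, Vax2, Cdx2, Six3, Foxb2, Gata2, Otx1 and Nkx6-2. Insl3, which encodes a hormone of the relaxin family rather than a regulator of transcription, was wholly covered too. All 20 had at least 9000 bp covered in both replicates. The peak of highest fold, 14.8, covered Olig1 (chromosome 16, 91265787 to 91273662), and the peak at neighbouring Olig2 (91218067 to 91230571) had 13.4, as had that at Onecut3 (chromosome 10, 80488491 to 80501928). Others of the 10 highest lay 90 bp from Hr, over Gp1bb and Gm49601, 281 bp from Prdm12, 12254 bp from Zfp316, and over Neurog3, Gfy with Pth2, and Foxa2.

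Promoters and CpG-rich sequence held far more of the mark than their length would give. Of 18681 replicated peaks, 6500 (34.8%) lay at promoters against 4.03% of randomly placed peaks, 8.64 times as many. CpG-rich segments were touched by 27.7% against 1.63% of placed peaks, 17.0 times as many. In the replicates' own lists the promoter share was 26.9 ± 3.25% and the CpG share 18.6 ± 3.39% (SD, n = 2). The CpG share was 55.4% among peaks of −log10 q of at least 5 and 16.24% in replicate 1's own list, which is the value without replicate 2. By length, 35.1% of covered bases were in promoters, which make up 3.08% of the sequence, 8.99% in other exons (3.09%), 26.4% in introns (34.5%) and 29.5% between genes (59.4%). CpG-rich promoters were marked in 22.8% of cases and other promoters in 5.75%, and 83.4% of marked genes had a CpG-rich promoter. A promoter window was at least 50% covered in 1297 genes and wholly covered in 145. Of the 3346 marked genes, 3188 were also marked in both replicates' own lists; with peaks of −log10 q of at least 5 the number of marked genes was 1654.

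Autosomes had between 4.29 and 12.9 replicated peaks per Mb, 7.16 over all 19. The X chromosome had 1527 peaks, 9.34 per Mb, 1.305 times the autosomal density (95% exact interval 1.24 to 1.37, counting error only). This lay within the range of the autosomes, 3 of which were denser. In the replicates' own lists X had 28.3 peaks per Mb in replicate 1, above every autosome, and 16.4 in replicate 2. X had a covered length of 3.73 kb per Mb in the replicated list, undercut by only 1 autosome. Its peaks were narrower, with a median of 302 bp against 446 bp, and 14.1% lay at promoters against 36.6% on autosomes. Among peaks of −log10 q of at least 5, X had 53 peaks and a density 0.178 times the autosomal one (0.133 to 0.233), the opposite direction. The Y chromosome had 0 replicated peaks.

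**Figure D3:**
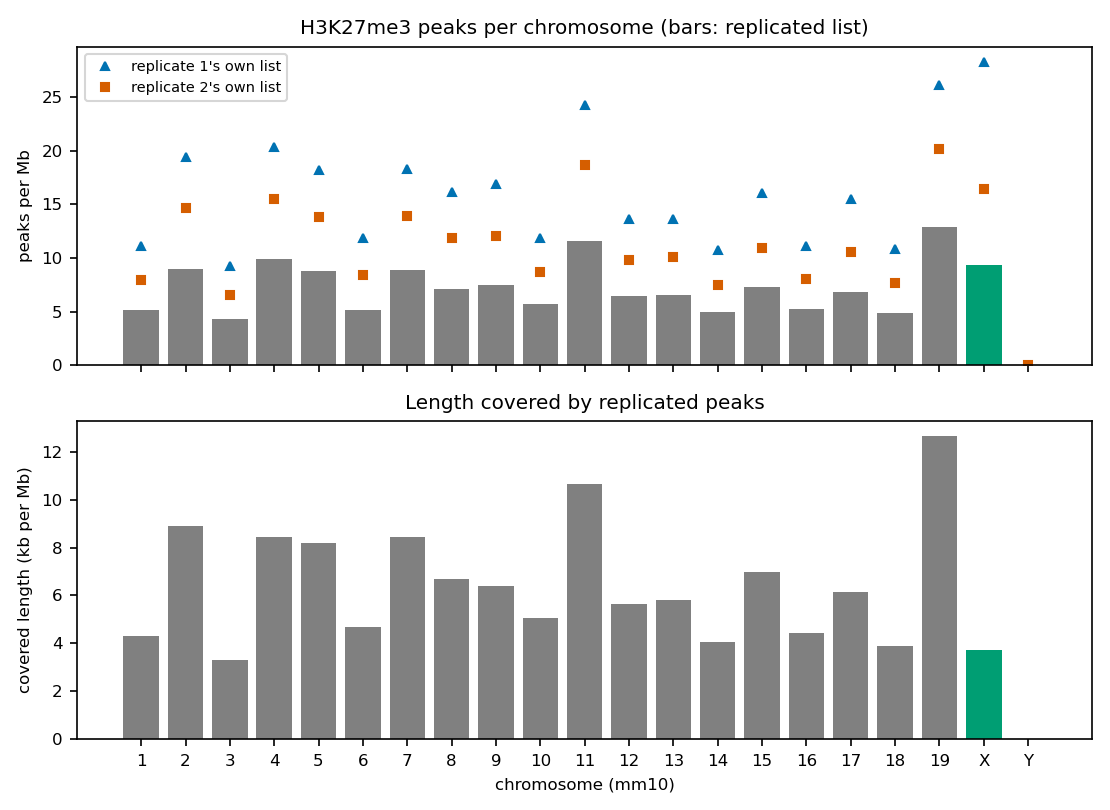
Peaks per Mb (upper panel) and covered kb per Mb (lower panel) on each chromosome, with bars for the replicated list (X in green) and symbols for each replicate's own list. X has 9.34 replicated peaks per Mb and 3.73 covered kb per Mb, and chromosome 19 has 12.9 replicated peaks per Mb, above all others in that list. In replicate 1's own list X is highest, with 28.3 peaks per Mb against 26.1 on chromosome 19.

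The replicates shared their strong peaks and differed in weak ones. Of replicate 2 peaks, 54.9% (95% exact interval 54.4 to 55.5%) lay in replicate 1 peaks, against 0.876% when placed at random. Of replicate 1 peaks, 32.0% (31.5 to 32.4%) lay in replicate 2 peaks, against 0.675%. Among peaks of −log10 q of at least 5, 93.0% of those of replicate 2 and 82.1% of those of replicate 1 lay in the other full list. Replicate 1 peaks that were not shared had a median fold of 3.14 and width of 236 bp, against 4.17 and 504 bp for shared ones. The shared bases made up 0.467 of the bases in either list (Jaccard index), against 0.0040 by random placement. Random placement leaves out any agreement that comes from input files listed for both replicates. Over 17183 overlapping pairs of peaks, Spearman's rho of the fold was 0.541 and Pearson's r of its log2 was 0.609, a description across peaks, which are not independent replicates. The shares moved by over 1.5 times with other rules: requiring 90% overlap gave 13.5% for replicate 1 and 33.1% for replicate 2, and limiting both lists to −log10 q of at least 5 gave 57.5% for replicate 1.

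**Figure D4:**
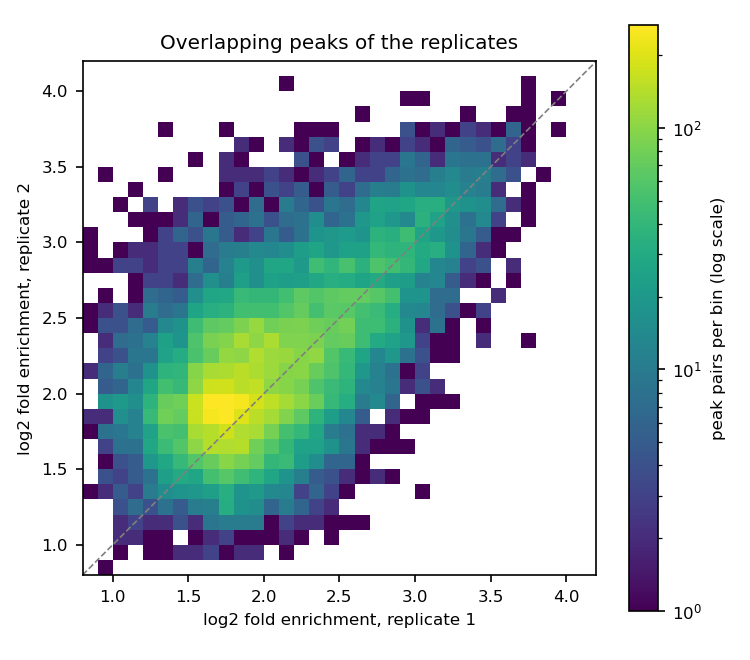
Fold over control, on a log2 scale, of 17183 overlapping peak pairs in replicate 1 (x axis) and replicate 2 (y axis), counted in square bins of 0.1 with a logarithmic colour scale. The dashed line marks equal folds, and the pairs spread around it with a Pearson's r of 0.609.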

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

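The comparisons with peaks found in both replicates' lists, Hox coding starts and X density under other lists were added after the data were seen. Of 162 alternatives for the gene lists, 141 kept direction and side of the threshold, though in 13 of these the share changed by over 1.5 times, and 10 of 18 lists kept both in all 9 settings. Another 10 changed direction against the remaining genes, none of them past the threshold. Of the 53 other alternatives, 22 kept their call or stayed within the bound used for their result. For numbers of marked genes the bound was a change of 1.5 times. For agreement of the replicates it was an interval that takes peaks or bases as independent. Such an interval is narrow, so a value outside it need not be a large change. The relation of Hox coverage to paralog number passed its permutation test in every setting tried, with rho from 0.777 to 0.844. That test does not allow for domains shared by neighbouring genes. The density of peaks on X relative to autosomes reversed with −log10 q of at least 5 (0.178), was 1.63 in the pooled list, and ranged from 1.46 to 1.85 without replicate 1 or 2. For the exceptions the cause was not tested unless a value below shows it. Read depth is unknown and limits which weak peaks could be called.

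Restricting peaks to −log10 q of at least 5 gave shared shares of 57.5% (replicate 1) and 73.4% (replicate 2), a Jaccard index of 0.635, rho of 0.506 between replicates, 1654 marked genes, 46.1% of peaks at promoters, 55.4% at CpG-rich segments and a longest domain of 70.9 kb. In that setting marked shares were 16.7% for pan-neural genes (exact adjusted p = 0.142), 33.3% for pluripotency genes (0.0146) and 0% for housekeeping genes (0.31). Shared shares were 41.6% and 64.3% with 1 bp of overlap, 13.5% and 33.1% with 90%, and 39.6% and 50.4% with lists of equal length. The Jaccard index was 0.500 with equal lists and 0.528 with peaks joined, and rho was 0.659 when peaks overlapped by 50% of both. Housekeeping genes, at 0%, lost their call with a 1 kb window (0.0613), 500 bp of coverage (0.0847) and peaks in both lists (0.0581), where fewer other genes are marked. CpG-rich promoters alone gave 44.4% of imprinted genes (0.0714), 60% of kinase inhibitors (0.112) and 0 of 1 olfactory receptor gene (1), and a 1 kb window 33.3% of kinase inhibitors (0.24). Promoter shares were 24.4% and 47.8% with windows of 1 and 5 kb, and from 24.6 to 29.2% without replicate 2 or 1. CpG shares were 23.9% in the pooled list, 31.7% for peaks in both lists, and from 16.24 to 21.04% without replicate 2 or 1. Pluripotency genes ranged from 33.3 to 50% without replicate 1 or 2. Glial genes, at 7.14%, were above the remaining genes in the pooled list and with a 5 kb window (21.4% each), and ranged from 14.3 to 28.6% without replicate 1 or 2. Genes of blood, vessels and connective tissue, at 15% and just below the remaining genes, were above them in the pooled list (20%), with −log10 q of at least 5 (10%), and at an unchanged 15% with a 1 kb window, 500 bp of coverage and peaks in both lists. Their share was 100% of 2 genes with CpG-rich promoters, and from 15 to 20% without replicate 2 or 1. The longest domain was 81.2 kb with a joining distance of 1 kb, 222.6 kb with 10 kb and 94.4 kb for peaks in both lists.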

Other observations

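The mark was also frequent in gene families outside the fixed lists. The families were defined, and the X density under other lists compared, after the main results had been seen. Of 355 families of at least 8 genes whose symbols share a stem, 40 had a higher marked share than other genes and 12 a lower one (Fisher's exact test, Benjamini-Hochberg over the 355). Among the higher ones were all 8 Grm genes, which encode metabotropic glutamate receptors (exact adjusted p = 1.15e-05), 11 of 14 Htr genes for serotonin receptors (1.15e-05), 7 of 8 Kcna and 7 of 8 Kcnh potassium channel genes (3.36e-04 each), and 9 of 14 Cacna calcium channel genes (8.88e-04). Kcnk with 10 of 14 (1.10e-04), Kcnj with 8 of 15 (0.00806), Fzd with 6 of 10 (0.0162), Gpr with 21 of 73 (0.0251) and Cacng with 5 of 8 (0.0254) passed too. Families that did not pass included Scn with 5 of 14 (exact adjusted p = 0.188), Trpc with 4 of 9 (0.152), Trpm with 2 of 8 (0.637) and Chrna with 2 of 9 (0.799). The counts in the replicates' own lists were 8 and 8 for Grm and 11 and 11 for Htr. Collagen genes were marked in 23 of 45 cases (1.44e-06). All 14 Nkx, 9 Pax and 8 Lhx genes were marked and 17 of 19 Wnt genes, of which 9, 6, 8 and 13 are also in the fixed lists.

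Families below the rest included Vmn, the vomeronasal receptors, with 0 of 331 marked (5.37e-22), Zfp zinc finger genes with 19 of 394 (5.89e-09), histone genes under the stem Hist with 0 of 67 (5.17e-04), and Mrpl, the mitochondrial ribosomal proteins, with 0 of 49 (0.00594). Among CpG-rich promoters only, 28 of the 40 higher and 5 of the 12 lower families still passed, Zfp with 13 of 245 and Hist with 0 of 65 among them, and Vmn, with 2 such promoters, did not. Of the families named above, Fzd lost its call there, with 6 of 10 (exact adjusted p = 0.0809). A shared domain over neighbouring family members was tested as an explanation. Counting each run of members within 100 kb once left 87.5% of the higher families past the threshold. That share includes families with no such run, among them Pax, Grm and Lhx, whose counts could not change. Of families with runs, Nkx with 12 of 12, Wnt with 13 of 15 and Col with 20 of 42 stayed past the threshold. For these, shared domains are argued against as the whole cause. The families that lost their call were Cacng with 3 of 5 (exact adjusted p = 0.147), Lrrc with 17 of 63 (0.0918), and Hoxa, Hoxc and Hoxd, each reduced to 1 gene and no longer testable. Of the 12 lower families 6 stayed past it, Vmn, Zfp and Mrpl among them, and Hist did not, with 0 of 7 (exact adjusted p = 0.901). On simulated marks over the 355 families, 71.0% of families planted with 60% marked passed and shuffled marks gave a mean of 0. Marks were shuffled gene by gene, so this does not show how often neighbouring genes that share a domain would pass.

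The higher density of X peaks was weighed against repeats, weak calls and a spread mark. Reads in soft-masked repeats are argued against, since X remained 1.24 times as dense as the autosomes (1.15 to 1.33) among peaks with under 10% soft-masked bases. Repeated sequence that is not soft-masked stays open, since this filter does not remove it. A peak over a ribosomal RNA gene on chromosome 17, for example, had 5.23% of its bases soft-masked. Noise in weak calls stays open. Of weak X peaks of replicate 1, 12.9% lay in replicate 2 peaks (22.2% on autosomes), against at most 0.684% in 100 random placements. This is past the bound set beforehand for excluding noise. The bound was dropped after the value was seen, because 2 input files are listed for both replicates' lists and random placement does not show the overlap that noise in shared files would give. Noise independent between the replicates and spread evenly along the chromosome would not give 12.9%. Random placement does not show what unevenly spread noise would give. The excess was in weak peaks: the ratio fell to 0.178 at −log10 q of at least 5. A mark spread away from promoters also stays open, since 14.1% of X peaks lay at promoters against 36.6% on autosomes, which it needs but which weak calls could also give. The sexes of the embryos were mixed in the pools, and sex was not tested.

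The larger number of peaks in replicate 1 lay below −log10 q of 3. The ratio of replicate 1 to replicate 2 was 1.03 at −log10 q of at least 5, and 2.05 below 2, so weak peaks near the calling threshold may account for the difference, while depth, which is unknown, stays open as the reason for them.

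The pooled list was shorter than either replicate list. At a fold of 8 to 9 the median −log10 p was 21.7 in the pooled list, 22.1 in replicate 1 and 21.2 in replicate 2. Several peaks had strong significance at low fold. On chromosome 17, peaks at 39843070 to 39846781 and 39847996 to 39848899 had folds of 2.27 and 2.09 with −log10 p of 43.8 and 36.0, over the annotated ribosomal RNA gene CT010467.1. The lowest p of the replicated list, −log10 p of 54.6, belonged to a 391 bp peak of fold 5.81 inside Cdk8 on chromosome 5 (146261094 to 146261484). These genes were picked after their values were seen.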
